A study of Caulobacter vibrioides with 4 samples.

How the data were processed

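PhoB binding was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in Caulobacter crescentus NA1000, the wild type, and in a strain without pstS. Per the labels' protocols, cultures grew in PYE medium at 30 °C to mid-log phase at an optical density of about 0.5, were crosslinked with 1% formaldehyde for 10 min, and were sonicated to fragments averaging 0.3 to 0.5 kbp. A rabbit polyclonal antibody raised against PhoB was used for the precipitation, and 2% of each lysate was kept as total input, per the labels' protocols. The 4 samples were 1 PhoB ChIP library and 1 input library per genotype, grouped by the genotype and library kind in the labels.

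The submitters' processing notes name CASAVA 1.8.2, Bowtie without a version, and MACS2 2.1.1.20160309.6. Per the file headers, MACS2 peaks at q = 0.05 were listed for each genotype. The genome build was not given in the sources used here. The deposited columns were the start, end, length and summit of each peak in bp, the pileup at the summit (a coverage signal), the fold enrichment at the summit (a ratio), and the −log10 p-value and −log10 q-value, per the file headers. Fold enrichment is the authors' own value per peak, and it was used to describe, rank or filter peaks within a list. Folds of overlapping peaks in the wild type and pstS deletion lists are set side by side as listed. No scaling between the libraries was made here, so such pairs do not measure a change in binding. Each list came from 1 library, so replicate calls could not be compared.

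The background behind each peak was recovered as (pileup + 1) / fold − 1, where 1 is the pseudocount of MACS2. The Poisson p-value computed from the pileup and this background matched the deposited p-value within 1% for all 1457 wild type and all 1101 pstS deletion peaks. The lowest background, which MACS2 sets from the genome-wide average, was 547 in the wild type list and 576 in the pstS deletion list. Read totals per library were not analysed here, so these floors are the only measure of depth used. At the strongest pstS deletion peak, the background was 699 under a pileup of 214534. A background taken from the same library over 10 kb would need fragments of at most 32.6 bp to be that low, which lies under the sheared length, so the background was not taken from the same library over that window. The pileup exceeded 1000 at 1090 wild type and 922 pstS deletion peaks. With fragments of 500 bp and at most 1 read per position and strand, the upper bound would be 1000. The stated lengths are averages, so longer fragments could raise this bound. The highest pileups, 56697 in the wild type and 214534 in the pstS deletion, lay far above it. Repeated reads at a position were therefore counted, and PCR copies can raise pileup and fold.

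Gene names and neighbours came from the RefSeq gene table of assembly ASM2200v1, which holds 4097 genes on 1 chromosome, 671 of them with a symbol. None of its coordinates are printed, and all positions are those of the deposited lists. Whether the lists use the same frame was tested by moving all summits. The share between genes was 35.9% (wild type) and 45.6% (pstS deletion) without a move, 10.7% and 12.1% after a move of −200 bp, and 10.8% and 12.1% after a move of 200 bp. The table gave no strand, product text or sequence. Genes were therefore scored for a summit at either end, from 400 bp outside to 100 bp inside, in place of the planned window at the gene start. Searches for Pho boxes, CtrA-type motifs and GANTC sites were not run. Planned lists of TonB-dependent receptors, phosphate enzymes and transporters, and regulators by product text were not analysed here, and flagellar, chemotaxis, ribosomal protein, tRNA and rRNA lists were built from symbols and gene types.

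Peaks of the lists were compared with bedtools 2.31.1 at a minimum overlap of 1 bp. The overlap was set beside 10000 rotations of a list around the circular chromosome, each by at least 10 kb. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Each gene list was set beside 10000 random gene lists of the same size, as planned. Further references were added after seeing the data. One was 10000 draws of protein-coding genes with like gaps beside them, because summits concentrate in gaps. Another was 4057 copies of the list moved along the gene order with its spacing kept, because neighbouring genes share peaks. The moved copies were added last, after the gap-matched result for ribosomal protein genes was seen. These references describe the lists, and no test between genotypes was made, as each genotype had 1 library. Intervals, rotations and lists were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. On simulated data, the scripts recovered 500 of 500 planted overlaps, 400 of 400 planted summits between genes, and 50 of 50 planted genes.

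The rule for named genes was fixed before the data were examined: the 15 highest-fold peaks of each list, the 10 highest-fold peaks found in each list alone, up to 30 genes of the fixed lists with the strongest peaks, and pstS and phoB. The table has no gene with the symbol pstS, so no value is given for it. Among the 30 genes, several tRNA and rRNA genes are given by count only. Weaker genes of the fixed lists, among them ctrA, sciP, lon, clpX, pilA, rsaA and ppk1, were named outside this rule. Alternatives covered stricter thresholds, other definitions of overlap, lists of equal length, other windows at gene ends, and peak midpoints. The fold of at least 5 used for the strongest peaks was chosen after seeing the data.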

Results

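PhoB, the response regulator that controls phosphate-starvation genes in bacteria, was mapped across the chromosome of Caulobacter crescentus NA1000 and of a strain without pstS, the gene of the phosphate-binding protein of the Pst transporter. The comparison asks where PhoB bound in wild type cells and where it bound when Pst was disrupted, a state known to activate the Pho regulon in bacteria. Each genotype had 1 PhoB ChIP library and 1 input library, 4 in all. There were no replicates, so differences between the lists could not be set against replicate error. Folds were not scaled between the libraries here, so a pair of folds does not by itself measure a change in binding. Positions are in bp of the single chromosome as the deposited lists give them.

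The strongest PhoB peak of both genotypes lay between phoR, the sensor kinase gene of the Pho system, and pstC, a permease gene of the Pst transporter. Its fold enrichment, the authors' own value per peak, was listed at 85.0 in the wild type (summit 305918) and 306 in the pstS deletion (summit 305921). The pileup there was 56697 and 214534. The wild type list held 1457 peaks with a median fold of 1.84, and the pstS deletion list held 1101 with a median of 1.87. The upper ends of the lists differed more than their medians: a fold of at least 10 was listed for 13 wild type and 47 pstS deletion peaks, and a fold of at least 20 for 3 and 18. Most peaks were weak, as 588 wild type and 473 pstS deletion peaks had a fold of at least 2. Peaks had a median length of 321 bp in the wild type and 326 bp in the pstS deletion, and together covered 14.5% and 11.2% of the chromosome.

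**Figure D1:**
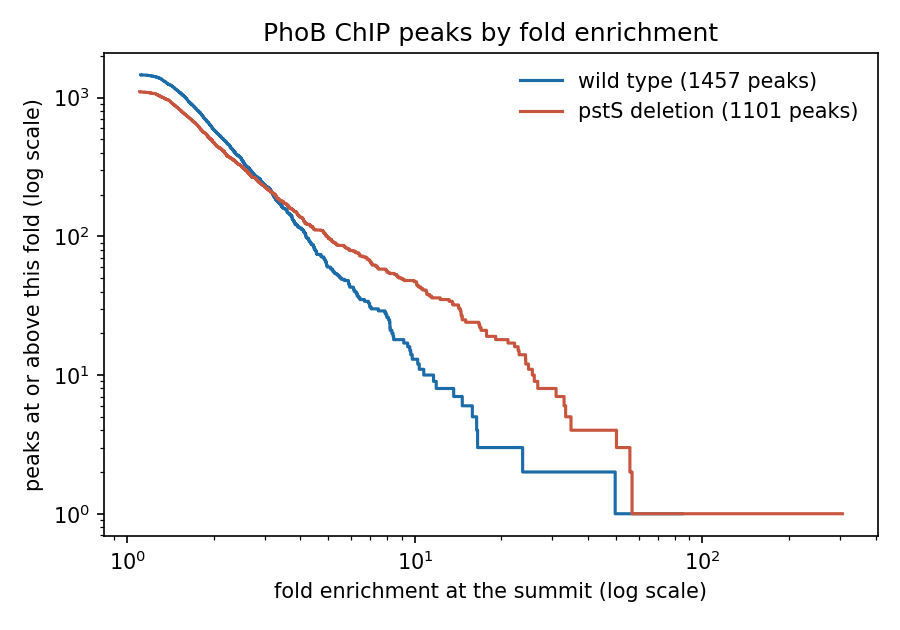
Number of PhoB ChIP peaks (vertical axis, log scale) at or above each fold enrichment (horizontal axis, log scale) in the wild type and pstS deletion lists. The wild type line is higher at low fold (1457 against 1101 peaks), and the pstS deletion line is higher at a fold of 5 (98 against 60 peaks), 10 (47 against 13) and 20 (18 against 3).

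After phoR and pstC, the strongest wild type peaks lay between CCNA_00168 and CCNA_00169 (fold 49.7), between CCNA_02740 and CCNA_02741 (23.7), and between CCNA_02895 and CCNA_02896 (16.5). A wide peak from 1439962 to 1444675 had its summit between secY, the gene of the main protein translocation channel, and adk, the adenylate kinase gene (15.8). For these last 2, the overlapping pstS deletion peaks had 8.49 and 13.1. The other wild type peaks between genes among the 15 highest lay between CCNA_03820 and CCNA_R0199 (14.6) and between CCNA_02901 and CCNA_02902 (13.6). Others lay between CCNA_00209 and CCNA_00210 (11.9), ldpE and CCNA_03906 (10.2), and CCNA_03816 and CCNA_03817 (9.67). For these 5, the overlapping pstS deletion peaks had 14.2, 17.7, 25.6, 22.9 and 14.6. Next to phoR and pstC, the strongest pstS deletion peaks lay between CCNA_R0024 and CCNA_01047 (56.9), CCNA_00759 and CCNA_R0120 (55.9), CCNA_00170 and CCNA_00171 (50.2), CCNA_00168 and CCNA_00169 (34.9), CCNA_01869 and CCNA_01870 (33.4), and CCNA_03954 and pbp1A, a penicillin-binding protein gene (33.0). The wild type list gave the overlapping peaks a fold of 4.09, 10.4, 6.96, 49.7, 4.18 and 8.18. CCNA_00520 and CCNA_00521 flanked a peak with a fold of 24.3 in the pstS deletion list and 2.42 in the wild type list. Also among the 15 highest, the peak between CCNA_02740 and CCNA_02741 had 31.0 in the pstS deletion and 23.7 in the wild type. The gap of CCNA_02308 and CCNA_02309 had 26.7 and 5.49, and that of CCNA_02231 and CCNA_02232 26.0 and 3.45. For CCNA_00209 and CCNA_00210 the folds were 25.6 and 11.9, and for CCNA_02910 and CCNA_02912 24.8 and 8.17. The peak in CCNA_03019 had 24.3 and 4.48, and that between CCNA_03191 and CCNA_03192 23.0 and 5.23. Of the 15 highest-fold peaks of each list, 5 overlapped, and all 15 of each list overlapped some peak of the other. Within genes, wild type peaks in CCNA_00842, CCNA_00326 and CCNA_01083 had a fold of 16.4, 11.6 and 10.7, and the overlapping pstS deletion peaks 7.47, 6.20 and 5.14, the last with its summit in CCNA_01085. The wild type peak in CCNA_00539 had 9.79 and the overlapping pstS deletion peak 4.10. The fifth, in CCNA_R0120, had 10.4, and its overlapping pstS deletion peak of 55.9 had its summit just outside that gene.

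Most sites were found in both genotypes. Of the wild type peaks, 967 (66.4%) overlapped a pstS deletion peak, against a median of 309 and a maximum of 362 after rotation. Of the pstS deletion peaks, 961 (87.3%) overlapped a wild type peak, against 302 and 357. Rotation does not keep the concentration of both lists between genes, so lists that share only this trait could also exceed the rotated counts. Summits of overlapping peaks lay a median of 17 bp apart. All 60 wild type peaks with a fold of at least 5 were shared, as were 93 of the 98 pstS deletion peaks at that fold. At a fold of at least 2 in both lists, 352 wild type and 353 pstS deletion peaks overlapped.

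Peaks in the wild type list alone numbered 490, with a median fold of 1.54. The highest lay in nrdJ, a ribonucleotide reductase gene, with a fold of 4.35 (summit 2109541), followed by CCNA_00576 (2.90), CCNA_00886 (2.79) and CCNA_03353 (2.72). All 10 of the highest were within genes. Peaks in the pstS deletion list alone numbered 140, with a median fold of 1.65, and 7 of the 10 highest were between genes. These lay between CCNA_00485 and CCNA_00486 (16.7), between CCNA_03439 and CCNA_03440 (9.17), between glnK, a PII nitrogen signalling gene, and glyQ, a glycyl-tRNA synthetase gene (6.74), between mutL, a mismatch repair gene, and CCNA_00732 (4.87), and between the kinase genes cckN and divJ (4.42), among others. Counts of unshared peaks depended on the threshold: with as many wild type as pstS deletion peaks, 269 wild type and 264 pstS deletion peaks were unshared. That these 2 counts are near each other follows from the equal list lengths, as 832 and 837 peaks overlapped.

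Summits concentrated between genes, which make up 8.90% of the chromosome. The share was 35.9% in the wild type (523 of 1457 peaks, 95% interval 33.4 to 38.4%) and 45.6% in the pstS deletion (502 of 1101, 42.6 to 48.6%), and the highest share after rotation was 11.9% and 12.1%. Among peaks with a fold of at least 5, the share was 46.7% in the wild type (28 of 60, 33.7 to 60.0%) and 75.5% in the pstS deletion (74 of 98, 65.8 to 83.6%). Of the 28 strong wild type peaks between genes, 22 overlapped a pstS deletion peak with a fold of at least 5, and of the 32 within genes, 14 did. In the other direction, 25 of the 74 strong pstS deletion peaks between genes and 11 of the 24 within genes overlapped a wild type peak with a fold of at least 5. Wild type peaks without a pstS deletion partner were between genes in 20.0% of cases (98 of 490, 16.5 to 23.8%), and shared wild type peaks in 44.0% (425 of 967, 40.8 to 47.1%). The unshared pstS deletion peaks were between genes in 43.6% of cases (61 of 140, 35.2 to 52.2%).

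**Figure D2:**
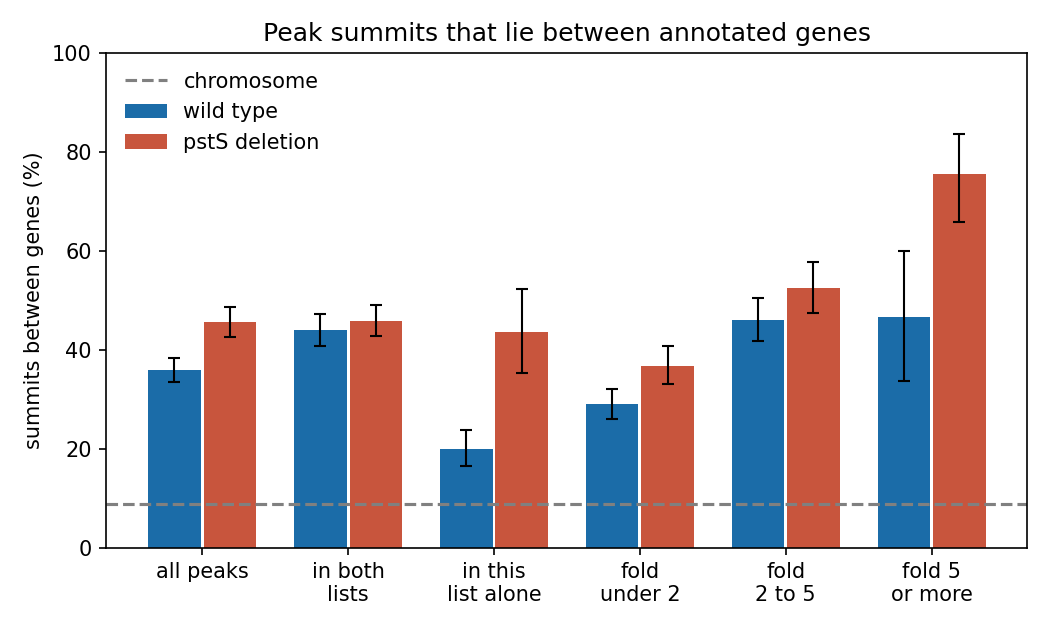
Share of peak summits between annotated genes (vertical axis, percent) for sets of peaks in the wild type and pstS deletion lists. Bars are shares, error bars are exact 95% binomial intervals, and the dashed line is the 8.90% of the chromosome that lies between genes. Wild type peaks in this list alone stand at 20.0%, under every other set shown.

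Genes of phosphate uptake and Pho regulation had peaks in both genotypes. Of the 23 symbols fixed, 8 were in the gene table. A peak at an end was found for 6 of the 8 in the wild type and 7 in the pstS deletion. The 6 genes shared 3 peaks: phoR and pstC as above, pstA and pstB (fold 2.16 in the wild type and 1.54 in the pstS deletion), and phoU and phoB (1.83 and 1.69, summits in phoU). The seventh gene, ppk1, a polyphosphate kinase gene, had a peak with a fold of 3.47 in the pstS deletion list alone. Among random lists the counts stood at percentiles 92.8 and 99.4, and 20.4% and 4.34% of copies of the list moved along the gene order had as many genes with a peak. Of draws with like gaps, 8.73% and 0.530% did. With a fold of at least 2, the counts were 4 and 3 of 8 (percentiles 94.3 and 86.0), so neither stood outside the central 95% of random lists.

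Cell cycle regulators had a peak at an end for 17 of 23 genes in the wild type and 18 in the pstS deletion. Percentiles among random lists were 99.4 and 99.99, and 1.68% and 0.123% of moved lists had as many. Of draws of genes with like gaps beside them, 12.1% and 1.98% had as many, so the wild type count did not stand apart from genes with such gaps. The strongest lay between lolD and mucR1, a transcriptional regulator gene (6.89 in the wild type and 5.08 in the pstS deletion). The peak between cpdR, an adaptor gene of ClpXP proteolysis, and CCNA_R0015 had a fold of 4.09 and 3.64. It also counts for CCNA_R0015 in the list of tRNA and rRNA genes. A peak between lon and clpX, both genes of ATP-dependent proteolysis, was listed at 3.79 in the pstS deletion, and the wild type peak that overlaps it at 1.60. The strongest wild type peaks at an end of these genes lay elsewhere, at 2.29 (clpX, summit 2185043) and 1.63 (lon, summit 2180952). At ctrA, the gene of the master cell cycle regulator, a pstS deletion peak with its summit between ldpD and ctrA (3.28) overlapped a wild type peak with its summit within ctrA (2.38). That wild type peak, from 3278564 to 3279996, overlapped 2 pstS deletion peaks in all. The summits therefore do not show that binding moved. The gap of flgE and sciP, the gene of a CtrA inhibitor, had peaks of 3.15 and 2.86. With a fold of at least 2, the counts were 8 and 10 (percentiles 88.8 and 99.2).

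Genes of nutrient stress signalling had a peak for 9 of 13 genes in the wild type and 7 in the pstS deletion (percentiles 93.1 and 79.5), and with a fold of at least 2 for 6 and 7 (percentiles 95.9 and 99.5). The strongest in the pstS deletion lay beside glnA, the glutamine synthetase gene (3.72 in the wild type and 17.0 in the pstS deletion). In the wild type the strongest was the peak of 4.17 near cspD, given next. A pstS deletion peak (8.65) had its summit between CCNA_R0037 and the cold-shock gene cspD. The overlapping wild type peak (4.17) had its summit between CCNA_R0036 and CCNA_R0037. Further peaks lay beside ptsP, a nitrogen phosphotransferase gene (2.50 and 4.32), and beside rsaA, the surface-layer protein gene (3.79 and 3.88). Stalk genes had a peak for 3 of 7 in each list (percentiles 40.1 and 52.5), with stpX, which encodes a stalk protein, at 1.55 and 5.90. Motility and pili genes had a peak for 10 and 6 of 15 (92.1 and 44.9), with pilA, the pilin gene, at 3.27 and 3.29. With the peak interval in place of the summit, the motility and pili counts were 12 and 11, and with a fold of at least 2 they were 5 and 4 (percentiles 80.4 and 72.0). Division, envelope and polarity genes had a peak for 13 and 10 of 21 (89.5 and 70.3), flagellar genes for 20 and 13 of 43 (42.4 and 5.98), and chemotaxis genes for 11 and 8 of 14 (98.8 and 87.1). As many genes were reached by 5.15% and 26.3% of moved chemotaxis lists, and by 0.770% and 7.99% of draws with like gaps. With a fold of at least 2, the chemotaxis counts were 7 and 3 (percentiles 98.0 and 53.2), and with a window of 200 bp outside and 50 bp inside 8 and 5. At a fold of at least 2, division, envelope and polarity genes numbered 3 in each list (percentiles 16.5 and 24.5, under the random medians of 5 and 4), stalk genes 0 and 2 (7.46 and 69.4), and flagellar genes 10 and 7 (48.6 and 23.9). For each of the other 5 lists of this paragraph, at least 13.2% of moved lists and 18.4% of draws with like gaps reached the count over all peaks in either genotype. The flagellin genes fljN and fljO flanked a peak of 7.46 and 10.3, and a peak in CCNA_00957 beside flhA, an export gene of the flagellum, had 9.44 and 5.20. A peak beside flaY had 2.85 and 7.10, one beside cheE 2.56 and 6.98, and one in cheD 4.25 and 2.84.

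The tRNA and rRNA genes stood furthest from random lists. A peak lay at an end of 49 of the 57 genes in the wild type and 47 in the pstS deletion, 47 of them in both, against random medians of 28 and 24. None of the 4057 moved lists had as many, with maxima of 44 and 40. The genes with a peak shared 38 peaks in the wild type and 39 in the pstS deletion. The peak beside CCNA_R0024 belongs here, with a fold of 4.09 in the wild type and 56.9 in the pstS deletion. Beside CCNA_R0047 the folds were 3.59 and 10.9, and beside CCNA_R0058, in the other direction, 5.89 and 3.28. With a fold of at least 2, the counts were 40 and 29, against random medians of 14 and 12. Ribosomal protein genes had a peak for 16 and 20 of 26 (percentiles 91.3 and 100.0), and 22.6% and 0.616% of moved lists had as many. With the peak interval in place of the summit, the count was 25 in both lists, and with a fold of at least 2 it was 9 in both (percentiles 89.8 and 94.5). With a window of 200 bp outside and 50 bp inside, it was 10 and 12. The genes counted in the pstS deletion alone were rpsM, rplO, rpsE, rpmD and rpsS. Their pstS deletion summits lay inside wild type peaks, from 1439962 to 1444675 or, for rpsS, from 1433016 to 1434459. The summit counts thus depend on how each list divided wide peaks. A peak in rplF, at an end of rpsH, had a fold of 4.02 in the wild type and 10.2 in the pstS deletion. A pstS deletion peak with its summit in rplC, at an end of rplD, had 5.92, and the overlapping wild type peak 2.12. In the whole table, 1996 genes had a wild type peak at an end and 1745 a pstS deletion peak, 1517 of them in both lists.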

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

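Of 104 values recomputed under alternatives, 62 stayed within 1.5 times the count, or within the 95% interval of the share, and 42 did not. The fold of at least 5, and a fold of at least 2 in a list against every peak of the other, were chosen after seeing the data. Peak numbers fell to 588 (wild type) and 473 (pstS deletion) at a fold of at least 2, to 237 and 229 at 3, and to 60 and 98 at 5, where the order of the genotypes turned. With a fold of at least 2 in both lists, 352 wild type and 353 pstS deletion peaks were shared and 236 wild type peaks unshared. Against every peak of the other list, peaks with a fold of at least 2 were shared in 537 and 430 cases and unshared in 51 and 43. Lists of equal length left 269 and 264 unshared, near each other by construction. Unshared pstS deletion peaks numbered 221 at 50% reciprocal overlap and 244 with summits within 100 bp. At a fold of at least 2, genes with a peak at an end numbered 1003 and 886. In the wild type this setting left 8 cell cycle, 3 division, 0 stalk, 5 motility, 10 flagellar, 7 chemotaxis and 9 ribosomal protein genes, and in the pstS deletion 3 phosphate, 10 cell cycle, 3 division, 7 flagellar, 3 chemotaxis, 9 ribosomal protein, and 29 tRNA and rRNA genes. Window changes moved ribosomal protein genes to 10 (wild type, narrow window), 25 (wild type, peak interval) and 12 (pstS deletion, narrow window), chemotaxis genes to 5 (pstS deletion, narrow window), and motility genes to 11 (pstS deletion, peak interval). Between genes lay 32.3% and 40.2% of peak midpoints, and 46.1% and 57.3% of summits with a fold of at least 2. Stricter thresholds hold fewer peaks by construction; for the other changes the cause was not tested. Alternatives for motif shares were not run, as no genome sequence was used. No paired analysis was possible because each genotype had 1 ChIP library.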

Other observations

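In this part, the test of the gaps beside tRNA and rRNA genes was set before its result was seen, and the other tests were chosen after. Several genes outside the fixed lists, chosen after their values were seen, flanked strong pstS deletion peaks. A peak between exbB, a gene that energises outer membrane transport, and CCNA_02422 had a fold of 21.1 in the pstS deletion list, and the wild type peaks that overlap it reached 2.20. The gap of chvT and mrrA held a peak of 13.5 and 2.51, the gap of CCNA_02320 and metZ one of 14.4 and 3.82, and the gap of cgtA, a GTPase gene, and CCNA_00318 one of 11.3 and 4.36. Beside lpxC, an enzyme gene of lipid A synthesis, the peak had a fold of 5.13 and 1.72. Other peaks at genes with a symbol were higher in the wild type. These lay in rtrB (6.16 in the wild type and 3.87 in the pstS deletion), beside tolQ (5.34 and 2.92) and in vapC (5.09 and 2.39). Non-coding RNA genes had a peak at an end for 82 of 151 in the wild type and 72 in the pstS deletion, or 54.3% and 47.7%, against 47.9% and 41.8% of protein-coding genes. No interval, draws with like gaps or moved lists were computed for these shares, so they do not establish an excess.

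Wild type peaks without a pstS deletion partner lay within genes more often than shared ones, with 20.0% and 44.0% between genes. Weakness may not account for this: shared wild type peaks drawn to the same fold had 39.2% between genes (34.9 to 43.5% over 10000 draws). Positions without regard to genes reached 14.3% at most in a set of 10000 rotations and 14.5% in another. The unshared wild type peaks with a fold under 2 had 20.3% between genes (89 of 439). The stronger ones, with a fold of at least 2, had a like share, but they were few and their rotated range was wider. Of these, 17.6% (9 of 51) lay between genes, and 335 of 10000 rotations reached that share. The background floor of the pstS deletion list was 1.05 times that of the wild type. It cannot decide whether weak peaks were missed there, because the floor follows the shallower of ChIP and input. The strongest peak also held 8.31% of the summed pileup at summits in the pstS deletion and 2.36% in the wild type. Weak peaks missed in the pstS deletion library remain open. So do signal within genes particular to the wild type library and a difference between the genotypes, with 1 library each.

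Peaks beside tRNA and rRNA genes were frequent in both lists. Long gaps beside these genes may not explain it, as 0% of 10000 draws of protein-coding genes with like gaps reached the count, with maxima of 47 (wild type) and 43 (pstS deletion). Signal at strongly transcribed genes whatever the antibody target could give such peaks, and would also be looked for at ribosomal protein genes. There, up to 0.590% of gap-matched draws reached the count, but with the spacing of the list kept, 22.6% of moved lists did so in the wild type and 0.616% in the pstS deletion. These counts use summits, and with peak intervals the ribosomal protein count was 25 in both lists. This explanation and PhoB binding cannot be told apart, because the 16 and 20 ribosomal protein genes share 9 and 13 peaks and no library without PhoB was analysed here.

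The background behind the peaks fell with distance from the first base of the coordinates. Its median within 250 kb was 795 in the wild type and 845 in the pstS deletion, and in the farthest 250 kb bin, up to 2000 kb, it was 554 and 625. A wave fitted along the circle had its top at −42.6 kb in the pstS deletion (95% interval −132 to 58.7 kb over 2000 resamples of 100 kb blocks). In the wild type the top lay at 13.1 kb (−59.1 to 88.4 kb). Copy number falling from the replication origin is a candidate explanation. The wave was fitted to the same background values, so it locates the fall and does not test this explanation. Without the peaks at the floor, Spearman's rho across peaks, which are not independent replicates, was −0.61 (wild type) and −0.60 (pstS deletion, −0.66 to −0.48), which argues against the floor as the whole source. An earlier comparison with 1000 rotations was set aside after its result was seen, since small rotations keep a smooth trend. When the rotations were drawn again, 5 (wild type) and 13 (pstS deletion) of 1000 gave a rho as low. The position of the origin in these coordinates was not measured here.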
